A study of Rattus norvegicus with 15 samples.

How the data were processed

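Kidneys of 5-week-old rats were profiled on 15 single-channel oligonucleotide arrays of 3 designs (A, B and C), 5 arrays per design. Strain was taken from the description of each sample. On designs B and C arrays 1 to 3 are described as Dahl S and arrays 4 and 5 as congenic for chromosome 10. On design A all 5 arrays are described as Dahl S. Because arrays 4 and 5 carry the numbers of the congenic kidneys of the other designs, their strain was treated as unsettled and they entered no comparison between strains. The labels do not say whether the kidneys of a strain came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The donor strain and the extent of the segment are not given in the sources used here.

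The values deposited by the authors are a linear signal intensity per probe set, never negative, between 0 and 92415. The software and the steps that made them are not given in the sources used here. From the values, each array had already been scaled, since the mean without the top and bottom 2% of the values lay between 1000.6 and 1001.3 on every array. That scale was kept. Whether a background was subtracted stays unknown.

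Each design was processed within its own table. Values were raised to a floor at the 25th percentile of the 5 arrays of the design (85.1 on A, 140.1 on B and 153.6 on C) and taken to log2. Probe sets whose mean over the 5 arrays reached the median of all values (319.5 on A, 485.8 on B and 510.3 on C) were tested, and the 59 control probe sets of each design were left out. This left 4411 of 8799 probe sets on A, 4385 of 8791 on B and 4420 of 8789 on C. Gene symbols came from the annotation tables of the array platforms and were updated through gene identifiers to the RefSeq annotation of rat assembly GRCr8. On A, 7006 probe sets had 1 symbol, 308 several and 1426 none, of which 6985 of those with 1 symbol were matched by identifier. On B the numbers were 5351, 38 and 3343, with 5333 matched, and on C 5821, 45 and 2864, with 5804 matched. Probe sets with several symbols were not named. The assembly was used only for names, for the chromosome of a gene and for gene order, since the array annotation names no build.

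The strains were compared on B and on C, 3 Dahl S against 2 congenic kidneys, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without an intensity trend and with Benjamini-Hochberg adjustment over the tested probe sets of the design. The threshold was an adjusted p of 0.05, and differences are congenic minus Dahl S. Fold differences are those of the log2 means after the floor. Where both congenic values lie below the floor the fold is a lower bound. Genes with several probe sets were represented by the probe set with the highest mean in the list and chromosome tests, so that Tbcd, whose other probe set is brighter, is not among the chromosome 10 genes counted at an unadjusted p under 0.01. Chromosome shares were compared with Fisher's exact test, two-sided, at an unadjusted p of 0.01, because fewer than 10 genes passed the adjusted threshold. The 24 lists (14 gene lists and 10 marker lists) were tested with camera, with an inter-gene correlation of 0.01, where at least 3 members were tested, which held for 19 lists and 32 tests. The lists arachidonic acid and P450, loop of Henle and distal tubule, blood, adrenal, and skeletal muscle had fewer members on each design and were not tested. The gene order test drew 100000 random sets.

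Named genes were chosen by a rule fixed before the data were examined. Where fewer than 10 named probe sets passed on a design, the 12 with the smallest p among those whose strain values did not overlap were named. To these were added chromosome 10 genes past an adjusted p of 0.05 over chromosome 10 alone, and from each list the members past the threshold or otherwise the 3 with the smallest p. On array A the members of the pressor hormone, salt transport and chromosome 10 candidate lists were described. Of the probe sets without a name, those past the threshold were given by identifier.

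The procedure was tested on simulated data, with 200 probe sets changed in each of 20 simulations. For array B (4385 probe sets) it recovered 71.6% of the changes of 1 on the log2 scale and 97.2% of those of 2, with a mean of 9.85 false calls. For array C (4420 probe sets) it recovered 77.6% and 98.6%, with 9.6 false calls. The noise was independent per probe set, and Benjamini-Hochberg adjustment is stricter where fewer probe sets change. The data gave 4 calls on array B and 0 on array C, so these recovery rates do not carry over to them. The chromosome 10 test was simulated separately, with 20 probe sets raised by 2 on the log2 scale and independent noise per probe set. It found changes placed on chromosome 10 in 20 of 20 simulations for each array. It gave a p under 0.05 in 1 of 20 (array B) and 0 of 20 (array C) where the changes were placed anywhere. The chromosome 10 differences in the data are fewer and smaller, and genes may be correlated, so these rates do not carry over to them.

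The alternatives were quantile normalisation, median scaling, a floor at the 10th or 40th percentile, no filter or a filter at the 75th percentile, an intensity trend with robust variance, array quality weights, each array left out in turn, other thresholds for the chromosome test, and for the lists an estimated correlation and both designs in one matrix. One alternative was added after seeing the data, the chromosome test without Krt19.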

Results

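Gene expression was measured in kidneys of 5-week-old rats of the Dahl salt-sensitive strain (Dahl S), an inbred line whose blood pressure rises on a high-salt diet, and of a congenic strain made from it. A congenic strain carries a chromosome segment of a donor strain on an otherwise shared background, here on chromosome 10, so that kidneys of both strains can be compared for the effect of that segment. Total RNA was hybridised to 3 oligonucleotide array designs, named A, B and C here, with 5 arrays per design and 15 arrays in all. The arrays are numbered 1 to 5 on each design. On designs B and C, numbers 1 to 3 were Dahl S (n = 3) and numbers 4 and 5 congenic (n = 2). On design A, numbers 1 to 3 were Dahl S (n = 3), and the strain of numbers 4 and 5 was left open because their descriptions differ from those of the same numbers on the other designs. The number of arrays limits the precision of every comparison. The median signal intensity per array was between 294.5 and 334.3 on design A, between 472.8 and 519.5 on design B and between 491.3 and 524.4 on design C. Pairs of arrays of one strain correlated with a Spearman coefficient, across probe sets, of 0.951 to 0.963 on A, 0.940 to 0.954 on B and 0.930 to 0.955 on C. The other pairs correlated at 0.930 to 0.962 on A, 0.927 to 0.961 on B and 0.918 to 0.955 on C.

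On array B, Otud7b, a deubiquitinase that restrains NF-kB signalling, was at least 5.37-fold lower in the congenic kidneys. Its signal was 761 ± 137 in Dahl S kidneys (SD, n = 3) and 127 ± 2.33 in congenic kidneys (SD, n = 2), where both values lay below the floor of 140.1 (log2 difference −2.43, SE 0.18, limma adjusted p = 0.0233). Probe sets without a gene name made up the rest of the changes. The probe set rc_AI030650_at rose 2.64-fold, from 1207 ± 89.3 to 3182 ± 233 (adjusted p = 0.0442). The probe set rc_AA964274_at fell 4.84-fold, from 1102 ± 316 to 222 ± 14.6 (adjusted p = 0.0442). The probe set rc_AI008321_at fell from 1764 ± 258 to 215 ± 124, with 1 of the 2 congenic values below the floor (adjusted p = 0.0442). These 4 of 4385 tested probe sets, 1 higher and 3 lower, were the changes past the threshold.

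The other named genes with the smallest p on array B, chosen among those whose strain values did not overlap, did not pass the threshold. Among those on chromosome 10, signal was 1427 ± 56.8 in Dahl S and 2605 ± 37.9 in congenic kidneys for Scrn2 (log2 difference 0.87, SE 0.13, limma adjusted p = 0.231). Mllt6, a partner of the histone methyltransferase Dot1l, measured 1887 ± 182 against 3206 ± 138, with log2 differences of 0.77 for this probe set and 0.30, 0.18 and 0.06 for the other Mllt6 probe sets of the array. Vezf1, an endothelial zinc finger transcription factor, measured 650 ± 122 against 1199 ± 105, and Tbcd, a tubulin folding cofactor, 1594 ± 112 against 2419 ± 126 (log2 difference 0.60, and 0.19 for its other probe set). Krt19, a keratin of simple epithelia, measured 1641 ± 159 against 826 ± 301 (log2 difference −1.03, SE 0.24, adjusted p = 0.934). Elsewhere in the genome, Snai1, a repressor of E-cadherin, measured 950 ± 255 in Dahl S and 377 ± 61.9 in congenic kidneys. Gng2, a G protein gamma subunit, measured 671 ± 83.0 against 364 ± 39.3, Sh2d2a, an adapter of T cells, 582 ± 47.9 against 370 ± 9.33, and Zbtb7a, a transcriptional repressor, 735 ± 8.82 against 512 ± 0.636. The secreted proteins C1qtnf12 and Angpt4 measured 557 ± 66.3 against 934 ± 67.5 and 544 ± 41.3 against 843 ± 66.9. The adjusted p of these genes on array B was between 0.231 for Scrn2 and 0.998 for Zbtb7a.

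The strain comparison on array B used limma with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 153 probe sets (62 higher, 91 lower) where 219.2 would be expected by chance, and at p under 0.01 there were 27 (12 higher, 15 lower) against 43.9. Values of the strains did not overlap for 753 probe sets (17.2%), and chance gives 20%. With quantile normalisation 1 call was left, Otud7b, and without any 1 of the Dahl S arrays, or without congenic array 4, there was none, while without congenic array 5 there were 31. Otud7b lost its call with a floor at the 40th percentile (limma adjusted p = 0.216) and without a filter on low values (limma adjusted p = 0.254). Its call was kept with quantile normalisation, median scaling, a floor at the 10th percentile, an intensity trend with robust variance, and array quality weights. Without a Dahl S array the mean of Otud7b fell below the filter, so that it was not tested, and the log2 difference of rc_AI030650_at was then 1.35 to 1.45.

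**Figure D1:**
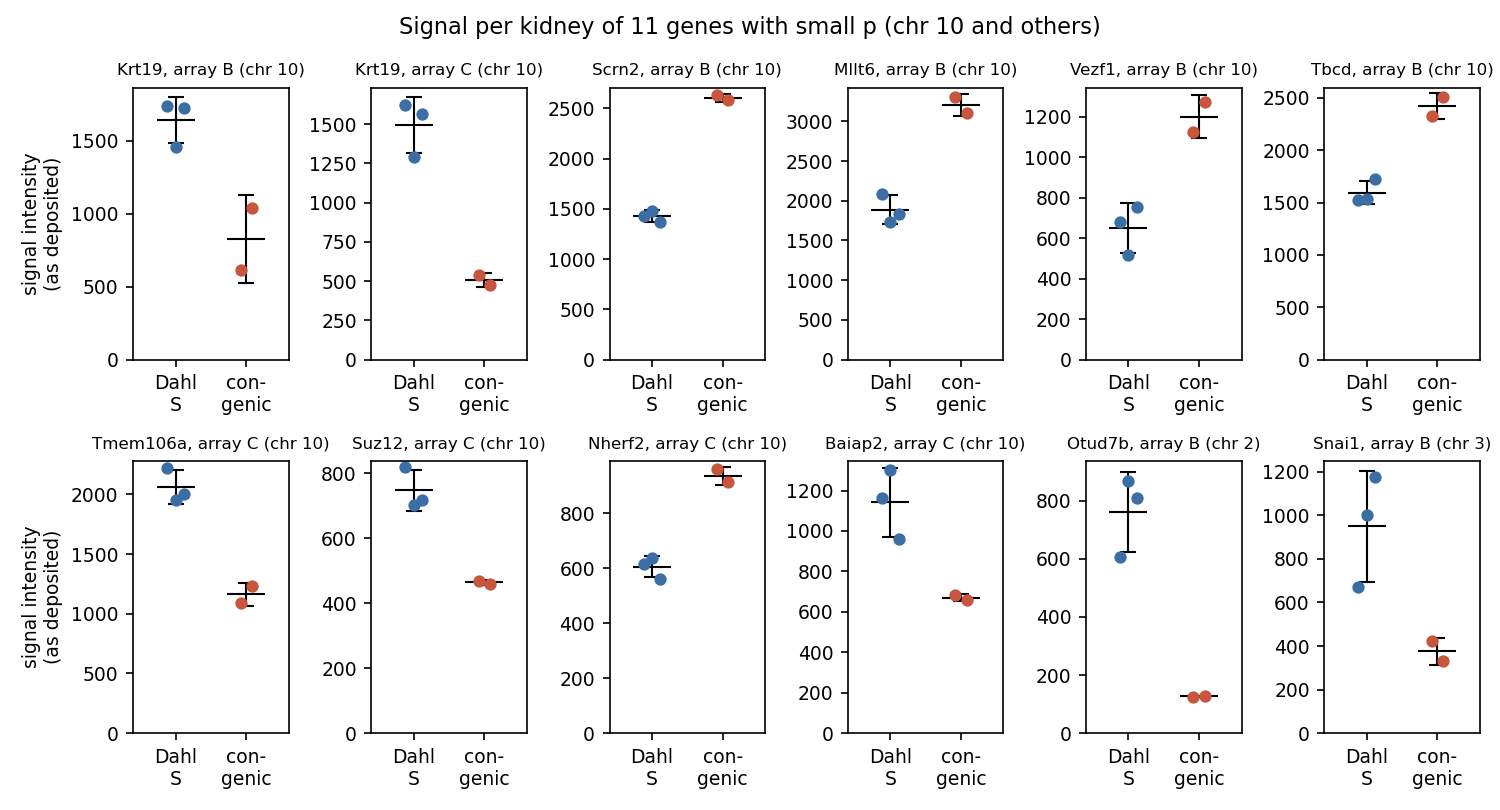
Signal intensity as deposited (vertical axes, linear, from 0) of 11 genes in each kidney, with Dahl S kidneys in blue (n = 3) and congenic kidneys in red (n = 2); Krt19 is shown on both array designs, horizontal bars are means and error bars are SD. The genes were chosen so that the points of the strains do not overlap, and of these genes Otud7b was past the adjusted threshold, at 125.4 and 128.7 in the congenic kidneys.

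On array C no gene passed the threshold, and the gene closest to it was Krt19. Its signal was 1494 ± 179 in Dahl S kidneys (SD, n = 3) and 507 ± 42.7 in congenic kidneys (SD, n = 2), a 2.94-fold difference (log2 difference −1.56, SE 0.16, limma adjusted p = 0.0754). Over the 278 tested chromosome 10 genes of array C alone, Krt19 passed (adjusted p = 0.00474), and it was the 1 gene of those that did. With an intensity trend and robust variance it also passed over all probe sets (adjusted p = 0.0329). It did not pass with quantile normalisation (limma adjusted p = 0.1) or without a filter on low values (adjusted p = 0.241). Without Dahl S array 1, 2 or 3 it did not pass either (adjusted p = 0.712, 0.17 and 0.418). With the filter at the 75th percentile it was not tested. Its log2 difference was −1.64 without congenic array 4 and −1.47 without congenic array 5.

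Other chromosome 10 genes with non-overlapping values on array C were Tmem106a, at 2061 ± 142 in Dahl S and 1164 ± 97.7 in congenic kidneys (log2 difference −0.82, SE 0.14, limma adjusted p = 0.739), and Suz12, a core subunit of the Polycomb repressive complex that methylates histone H3, at 746 ± 63.3 against 463 ± 8.20. Baiap2 measured 1142 ± 171 against 671 ± 16.8 (log2 difference −0.76, and −0.24 for its other probe set). Nherf2, a PDZ scaffold of the sodium-hydrogen exchanger Slc9a3, measured 605 ± 38.4 against 937 ± 32.9. On other chromosomes, Gjb2 (connexin 26) measured 14435 ± 1225 in Dahl S and 9313 ± 717 in congenic kidneys. Dlat, the acetyltransferase subunit of pyruvate dehydrogenase, measured 2074 ± 431 against 1018 ± 283, Klf3, a transcriptional repressor, 709 ± 10.0 against 470 ± 15.5, Pmm1, a phosphomannomutase, 692 ± 61.3 against 426 ± 27.6, and Ehd4, an endocytic recycling protein, 1420 ± 27.4 against 923 ± 75.6. Ppp1r11, an inhibitor of protein phosphatase, measured 2577 ± 128 against 3965 ± 154, and Rapsn, which clusters acetylcholine receptors, 463 ± 33.8 against 724 ± 17.0. The adjusted p of these genes other than Krt19 was 0.739 in each case.

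None of the 4420 probe sets tested on array C with limma passed the threshold. At an unadjusted p under 0.05 there were 274 (140 higher, 134 lower) where 221 would be expected by chance, and at p under 0.01 there were 48 (24 higher, 24 lower) against 44.2. Values of the strains did not overlap for 992 probe sets (22.4%), and chance gives 20%. Without a filter on low values there were 2 calls, Rps24 and rc_AI112208_at, with an intensity trend 1, Krt19, and without congenic array 5 there were 35.

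Genes on chromosome 10, which carries the congenic segment, were compared with genes on other chromosomes. At an unadjusted p under 0.01, the tests past it included 10 of 545 on chromosome 10 (1.84%) and 28 of 5369 elsewhere (0.522%), an odds ratio of 3.56 (95% confidence interval 1.54 to 7.61, Fisher's exact test, two-sided, p = 0.00179). The higher ones were Scrn2, Mllt6 and Vezf1 on array B and Nherf2 on array C. The lower ones were Krt19 on both designs and Tmem106a, Suz12, Baiap2 and Nsf on array C. Nsf, an ATPase of vesicle fusion with a signal of 1553 in Dahl S and 1116 in congenic kidneys, was named after its values were seen. Of 21 chromosomes tested, chromosome 10 alone passed after Benjamini-Hochberg adjustment (adjusted p = 0.0375). At an unadjusted p under 0.05 it held 44 of 545 tests (8.07%, 18 higher and 26 lower) against 212 of 5369 (3.95%), an odds ratio of 2.14 (adjusted p = 0.000736). On the other chromosomes both shares lay below those that chance gives at these thresholds. Part of each odds ratio therefore comes from few small p there. Genes tested on both designs count on each, so the 545 tests cover 490 genes, on the same kidney numbers. Fisher's exact test treats the tests as independent, which genes of the same kidneys are not. The intervals and p-values may therefore be too small, also within 1 design.

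Within array B the chromosome 10 share was 4 of 267 against 9 of 2581 (odds ratio 4.34, 95% confidence interval 0.971 to 15.7, Fisher's exact test p = 0.0273), and within array C 6 of 278 against 19 of 2788 (odds ratio 3.21, 1.04 to 8.46, p = 0.0213). On array B the share elsewhere (0.349%) lay below that expected by chance at this p. At an unadjusted p under 0.05 chromosome 10 there held 13 of 267 tests (4.87%), no more than chance gives, against 2.98% elsewhere. Krt19 counts on both designs. Without it the odds ratio for the chromosome 10 share of the changes, array B and C together, was 2.85 (Fisher's exact test, p = 0.0144). For the chromosome 10 share of the changes, array B alone, it was then 3.26 (exact p = 0.0942), and for the chromosome 10 share of the changes, array C alone, 2.68 (exact p = 0.0592), so neither design alone kept its call. On array B the call was also lost without a filter on low values (odds ratio 1.52, Fisher's exact test p = 0.388), at an unadjusted p under 0.05 (odds ratio 1.66, exact p = 0.0980), without Dahl S array 1 (exact p = 0.0569) and without Dahl S array 2 (exact p = 0.0677). On array C it was lost without Dahl S array 2 (Fisher's exact test p = 0.0565). Both designs together kept an exact p under 0.05 in each of these settings, without adjustment over the chromosomes. Called at an adjusted p under 0.05, Otud7b on chromosome 2 was the 1 named gene, which makes the odds ratio 0.

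**Figure D2:**
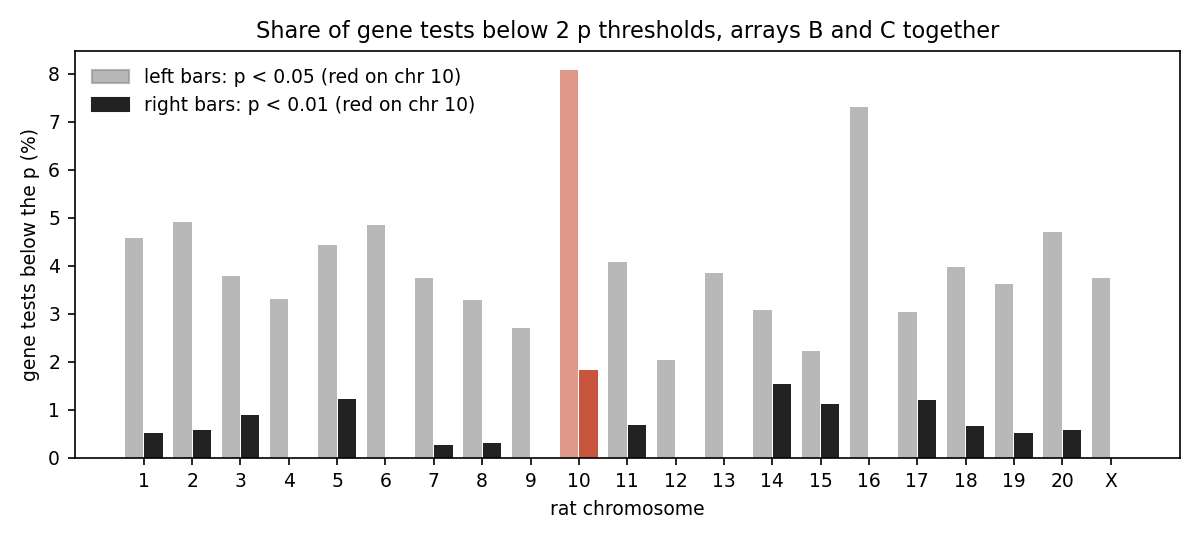
Share of gene tests (vertical axis, percent, from 0) below an unadjusted p of 0.05 (left bars) or 0.01 (right bars) on each rat chromosome (horizontal axis), arrays B and C together; chromosome 10 is in red. Chromosome 10 has the highest bar of each kind, at 8.07% and 1.84%.

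The 490 tested genes of chromosome 10 were also set in their order along the chromosome, taken from the rat assembly GRCr8. Of the 9 genes with an unadjusted p under 0.01, 8 lay past the midpoint of that order, and Nherf2 lay before it. Vezf1, Scrn2, Mllt6, Krt19 and Tmem106a followed each other at positions 297, 324, 329, 344 and 368. The spread of the 9 positions (SD 115.4) was not past the threshold against random draws of 9 genes (median SD 140.7, permutation test, one-sided, p = 0.166), nor was that of the genes with an unadjusted p under 0.05 (permutation p = 0.288). The share of tests with an unadjusted p under 0.05 was 5.26% from Aurka-ps1 to Pdlim4, 6.47% from P4ha2 to Gosr1, 11.9% from Blmh to Nbr1 and 8.70% from Tmem106a to Tbcd.

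**Figure D3:**
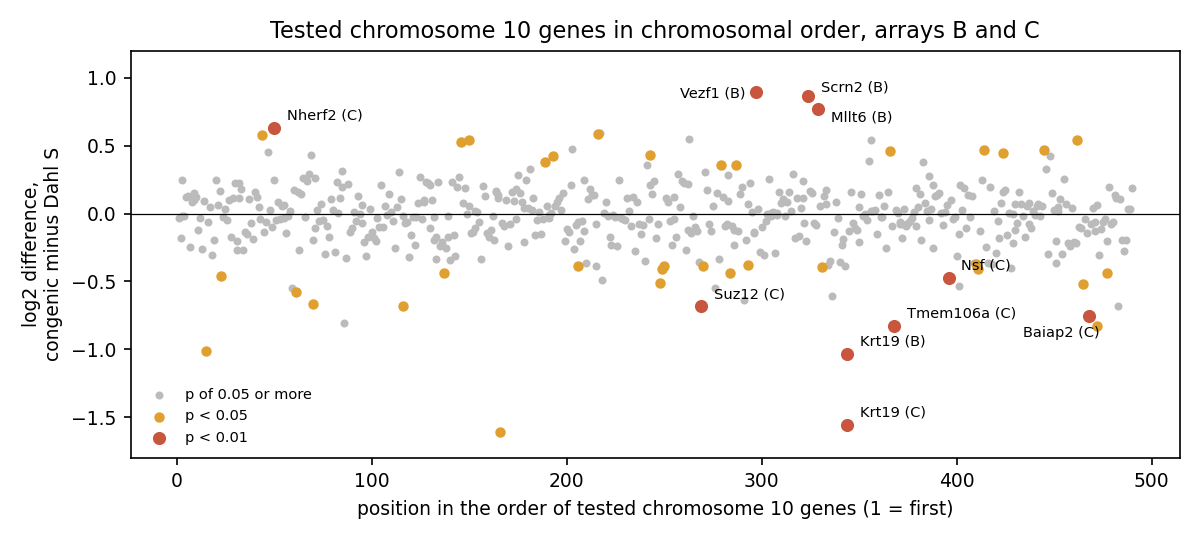
Log2 difference of congenic minus Dahl S (vertical axis) of each tested chromosome 10 gene, 1 point per gene and array design, against its position among the 490 tested genes (horizontal axis); colours give the unadjusted p of limma. The named points past 0.01 run from Nherf2 at position 50 to Baiap2 at position 468, with Krt19 lowest among them at −1.03 and −1.56.

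Of the gene lists fixed before the data were examined, ribosomal protein genes were lower as a group in the congenic kidneys on array C. All but 1 of the 12 tested members had a negative difference (median log2 difference −0.25, camera adjusted p = 0.00612). This call did not hold with an estimated correlation (adjusted p = 0.754 with an estimated correlation, unadjusted p = 0.138). Rps27 measured 23838 ± 2426 in Dahl S and 17443 ± 2591 in congenic kidneys, Rpl23 1470 ± 137 against 1116 ± 119, and Rpl30 574 ± 58.0 against 435 ± 32.0; none passed adjusted over the list alone (adjusted p = 0.135 each). On array B, 9 of 10 ribosomal protein genes had a negative difference, with a median of −0.12 (adjusted p = 0.282), and Rps21, Rps28 and Rplp1 had the smallest p. The call on array C was lost without Dahl S array 3 (adjusted p = 0.104), without congenic array 5 (adjusted p = 0.268) and without a filter on low values (adjusted p = 0.137). The 3′ over 5′ ratio of the GAPDH control on that array also differed between the strains, at 1.1 ± 0.00948 in Dahl S and 1.05 ± 0.0056 in congenic kidneys.

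Genes of antigen presentation and the interferon response did not pass as a list on either design (adjusted p = 0.0692 on each). On array C, 10 of 12 had a negative difference (median −0.20) and on array B 4 of 5 (median −0.39). The members with the smallest p were RT1-Bb, a class II histocompatibility chain, at 1619 ± 221 against 1079 ± 180 on array C, and the immunoproteasome subunits Psmb9, at 1076 ± 87.7 against 795 ± 47.8 on array B and 635 ± 97.3 against 452 ± 126 on array C, Psmb8, at 829 ± 119 against 554 ± 248 on array C, and Psmb10 on array B, with 1 congenic value below the floor. Ifi27, induced by interferon, measured 13383 ± 2632 against 10533 ± 4278 on array B. On array B the median difference of the list from Dahl S was −0.495 in congenic kidney 4 and 0.0368 in congenic kidney 5, and without kidney 4 the adjusted p was 0.891. The leukocyte markers of array B, C1qa, Laptm5 and Fcer1g, had medians of −0.604 and −0.0493 in the same kidneys (on array C the leukocyte markers had −0.234 and 0.285, and this list −0.291 and −0.153), and in Dahl S kidneys 1 to 3 of 0.283, −0.326 and 0.0424, where this list had 0.105, −0.114 and −0.0093. In the gene list MHC and interferon, array B, adjusted p = 0.00181 was reached without congenic array 5, and in the gene list MHC and interferon, array C, adjusted p = 0.0249 without Dahl S array 2. With all arrays both had adjusted p = 0.754 with an estimated correlation. With arrays B and C in one matrix, 12 of 15 members of this list (adjusted p = 0.00368) and 20 of 21 ribosomal protein genes (adjusted p = 0.000488) had a negative difference, and neither call held with an estimated correlation (adjusted p = 0.596 for each).

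Genes of renal salt transport did not move as a group. On array B 5 of 9 were lower and 4 higher (camera adjusted p = 0.6), and on array C 6 of 10 were lower and 4 higher (adjusted p = 0.877). The basolateral cotransporter Slc12a2 measured 911 ± 97.2 in Dahl S and 626 ± 59.3 in congenic kidneys on array B (adjusted p = 0.0989, adjusted over the list alone), and the kinase Wnk1 and the ubiquitin ligase Nedd4 had the next smallest p there, at 1312 ± 158 against 1050 ± 152 and 2136 ± 164 against 1791 ± 54.1. On array C the kinase Oxsr1 measured 670 ± 81.4 against 979 ± 262, the scaffold Nherf1 633 ± 122 against 855 ± 65.0 and the sodium pump subunit Atp1b1 38684 ± 3216 against 32193 ± 2667. Of the pressor hormone genes, array B tested the peptidases Enpep, at 3818 ± 646 against 4941 ± 1005, and Ece1, at 725 ± 56.1 against 674 ± 35.1, and the renin receptor Atp6ap2, at 7079 ± 334 against 6578 ± 1039 (adjusted p of the list 0.907), and array C the peptidase Mme alone. The chromosome 10 candidates tested were Wnk4, Stat3 and Slc4a1 on array B (adjusted p of the list 0.816) and Apoh, Igfbp4 and Stat3 on array C (adjusted p of the list 0.927). Of these, Apoh, a plasma lipoprotein component, measured 541 ± 52.8 against 750 ± 112 (adjusted p = 0.0647, adjusted over the list alone).

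Markers of kidney cell types did not pass as lists on either design. Krt19 was the collecting duct marker past the threshold adjusted over the list alone, on array B (adjusted p = 0.0115) and on array C (adjusted p = 5.115e-05), and the list itself gave 0.434 on array B and 0.0967 on array C. Without congenic array 4 the gene list collecting duct, array C, adjusted p = 0.0103, passed. With all arrays it had adjusted p = 0.754 with an estimated correlation. The other collecting duct markers on array B had log2 differences of 0.11 (Slc26a4) and −0.03 (Slc4a1), and those on array C of −0.23 (Atp6v1g3) and 0.36 (Aqp4). Tie1, an endothelial receptor, measured 665 ± 168 against 318 ± 93.6 on array C. Tie1 was past the threshold adjusted over the list alone (limma adjusted p = 0.0324), but not over all probe sets (adjusted p = 0.739). Sox17, an endothelial transcription factor named after its values were seen, measured 411 ± 277 against 1179 ± 208 on array C, with 1 Dahl S value below the floor (limma adjusted p = 0.0535, adjusted over the list alone). Of the 7 endothelial markers there 5 had a negative and 2 a positive difference (adjusted p of the list 0.877). On array B the endothelial list gave 0.77, with Ehd3, Tek and Cav1 at the smallest p. The podocyte protein Podxl measured 2677 ± 292 against 4147 ± 1356 on array B and 1087 ± 281 against 1566 ± 454 on array C, and its list gave 0.653 and 0.588, with Cd2ap and Itga8 on array B and Clic5 and Pdgfrb on array C next. The 8 proximal tubule markers on array C were split evenly by sign (adjusted p = 0.932), with Hnf4a, Ggt1 and Miox at the smallest p. Leukocyte markers gave 0.515 on array B (C1qa, Laptm5 and Fcer1g) and 0.653 on array C, where Cd3e measured 855 ± 70.4 against 1176 ± 194, and fat markers gave 0.42 on array C (Car3, Lipe and Adipoq).

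Lists of metabolism and growth did not pass either. Of fatty acid oxidation genes, all 5 on array B had a positive difference, led by Acaa1a at 4020 ± 191 against 4877 ± 34.8 and by Crat and Phyh (adjusted p = 0.282). Without a filter on low values the gene list fatty acid oxidation and peroxisome, array B, adjusted p = 0.0106, passed. With the filter it had adjusted p = 0.754 with an estimated correlation. On array C, Eci2, an enoyl-CoA isomerase, measured 2757 ± 398 against 1763 ± 68.7. Eci2 was past the threshold adjusted over the list alone (limma adjusted p = 0.0199), but not over all probe sets (adjusted p = 0.739). The list did not pass there (camera adjusted p = 0.42). Oxidative phosphorylation genes gave 0.653 on array B, where 8 of 12 had a positive difference and Sdha, Atp5mg and Ndufc2 had the smallest p, and 0.562 on array C, where 13 of 18 had a negative difference and Ndufa2, Ndufs1 and Atp5f1d had the smallest p. Sterol and lipid synthesis genes gave 0.555 on array B, with the regulator Srebf1 at 1617 ± 370 against 2292 ± 50.4, and 0.77 on array C, with the desaturase Scd2 at 4538 ± 468 against 3140 ± 439. Fibrosis genes gave 0.515 on array B and 0.282 on array C, and the basement membrane collagen Col4a1 measured 18239 ± 2086 against 14288 ± 1161 on array B and 7823 ± 1098 against 5952 ± 171 on array C, with Col1a2 at 14773 ± 2379 against 10734 ± 2599. Cell cycle genes gave 0.446 on array B, where Ccnd1 and Mki67 had the smallest p, and 0.515 on array C. Glutathione and oxidant defence genes on array C gave 0.515, with Sod2, Prdx1 and Ggt1 at the smallest p, and stress genes on array C gave 0.42, with the metallothionein Mt2A at 1045 ± 44.5 against 1344 ± 132. Circadian clock genes on array B gave 0.358, and the clock repressor Cry2 measured 1292 ± 268 against 1890 ± 59.2. All these list values are camera adjusted p over 32 tests, of which 1 passed, and with an estimated correlation none passed (lowest adjusted p = 0.754).

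Lists with fewer than 3 tested members on each design were described by gene. Cyp2e1, a cytochrome P450, measured 491 ± 93.9 in Dahl S and 848 ± 116 in congenic kidneys on array C (limma adjusted p = 0.739 over all probe sets), and Ptges, a prostaglandin E synthase, 2297 ± 111 against 2329 ± 108 on array B. Of loop and distal tubule genes, Cldn10 measured 17087 ± 526 against 19259 ± 1510 and Slc8a1 4080 ± 420 against 4616 ± 206 on array B, and Calb1 12898 ± 2161 against 15064 ± 224 on array C. With both designs in one matrix these 3 formed a list that did not pass (adjusted p = 0.154). The globin Hba-a1 measured 81850 ± 8152 against 88056 ± 6164 on array B, and the muscle genes Myh4 and Myl11 2410 ± 294 against 2678 ± 261 and 637 ± 39.2 against 649 ± 61.8 on array C. No adrenal gene was tested.

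Between arrays B and C, the log2 differences of the 600 genes tested on both correlated weakly across genes, which are not independent replicates (Pearson r = 0.219), and 55.5% had the same sign. Krt19 was lower on both designs. Of the 5 genes with an unadjusted p under 0.01 on either, all had the same sign on both designs, and these were Krt19, Gjb2, Klf3, Htra3 and Nherf2. Outside Krt19 their log2 differences on array B were small: −0.21 for Gjb2, −0.15 for Klf3, −0.04 for Htra3 and 0.25 for Nherf2. Arrays of the designs carry the same kidney numbers, so this compares probe sets and arrays and adds no animals. The other splits of the 5 kidneys into 3 and 2 reached a correlation of up to 0.206, and 5 of the 10 splits, the real one included, had as large a share of equal signs (highest of the others 57%). Without congenic array 4 the correlation for the same gene on arrays B and C was 0.0638, and without a filter on low values 0.11.

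On array A, no strains were compared, and levels were described in the 3 Dahl S kidneys. Of the salt transport genes, the sodium pump subunit Atp1b1 measured 44863 ± 3663 (SD, n = 3) and Umod, the uromodulin gene of the thick ascending limb, 34996 ± 4676. The potassium channel Kcnj1 measured 8568 ± 2120, the glucocorticoid-inactivating enzyme Hsd11b2 7794 ± 793, and the thiazide-sensitive cotransporter Slc12a3 4401 ± 1018. The loop cotransporter Slc12a1 gave 1014 ± 152, the sodium channel subunits Scnn1a and Scnn1g 1430 ± 185 and 768 ± 31.2, and the exchanger Slc9a3 657 ± 82.2. Of the pressor hormone genes, Klk1 (kallikrein) measured 12179 ± 921, Anpep 12138 ± 831, Avpr2, the vasopressin receptor of the collecting duct, 2580 ± 208, Agt (angiotensinogen) 1296 ± 86.0, Agtr1a 1226 ± 200 and Ace 401 ± 135. Of the chromosome 10 candidates, Ngfr gave 4505 ± 409, Kcnj16 1549 ± 162, Trpv1 849 ± 86.8, Stat5b 674 ± 135 and Nos2 412 ± 263. Levels of different probe sets depend on the probes and do not rank the genes by transcript number.

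The arrays numbered 4 and 5 on design A gave, for Stat5b, 1063.2 and 1167.8, for Trpv1 157.9 and 828.3, for Nos2 153.6 and 1306.3, for Ace 245.6 and 404.7, and for Slc9a3 1249.6 and 698.6. For Klk1 they gave 16532.8 and 12590.4, for Agt 897.1 and 1112, and for Stk39, a kinase of the salt cotransporters that measured 3155 ± 315 in Dahl S, 3771.6 and 4246.8.

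The control probe sets were compared by the ratio of signal at the ends of the transcript. The 3′ over 5′ ratio of actin was 1.28 ± 0.073 in Dahl S (SD, n = 3) and 1.33 ± 0.0358 in congenic kidneys (SD, n = 2) on array B, and 1.46 ± 0.0653 and 1.41 ± 0.0589 on array C. The ratio of GAPDH was 1.14 ± 0.0328 and 1.12 ± 0.0686 on array B. On array A the Dahl S kidneys gave 1.47 ± 0.0684 for actin and 1.07 ± 0.00391 for GAPDH. The arrays numbered 4 and 5 there, whose strain is not settled, gave 1.32 and 1.35 for actin and 1.04 and 1.04 for GAPDH. Each of these lay below every Dahl S array of that design.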

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

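One of the tests here, on the number of Krt19 probe sets, was chosen only after the result was seen. Krt19 on design A stood out because arrays outside every comparison lay below all 3 Dahl S arrays. The first Krt19 probe set measured 246.5 on array 4 and 365.4 on array 5, against 554.6, 516.3 and 561.6 in the Dahl S kidneys. The second measured 458.6 and 468.3, against 927.5, 787.2 and 968.4. Both Krt19 probe sets carry the same sequence identifier, so they are not independent. By chance 20% of probe sets have no overlap between 3 and 2 arrays. The other genes named by smallest p and present on design A, Dlat, Gjb2, Vezf1 and Ehd4, did not repeat their change on both arrays. Gjb2 gave 2682.9 and 1950.8, against 2361.9, 2179.7 and 2249.1. A Dlat probe set was higher, at 4230.7 and 3769.8 against 3338.4, 3565.3 and 3417.2. The strain of arrays 4 and 5 on this design is not settled, so these values enter no comparison and do not settle it.

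Lower Krt19 in the congenic kidneys was weighed as a pattern on arrays B and C. Krt19 was lower by more than 0.5 on the log2 scale, without overlap, in 2 probe sets on different designs. A fault of 1 probe set alone would not give both. These are the values by which Krt19 was named, so they are no separate test. Fewer collecting duct cells would lower the other markers of that cell type as well. The median log2 difference of the 4 others was 0.0377 (95% bootstrap interval −0.231 to 0.363), above −0.648, which is 0.5 of the mean Krt19 difference and was the bound set for this test. With 4 markers this interval is only the range of their values. Slc4a1 is also in the blood list, and Aqp4 measured 2051.1 and 889.6 in the congenic kidneys on array C. The values argue only against a shared fall of these 4 markers as large as that bound. Whether some collecting duct cells were fewer cannot be told from them. Regulation of Krt19 by the donor segment, or a sequence difference in its transcript that both probe sets share, may account for the lower Krt19 signal and was not tested.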

How the results depend on the processing

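The chromosome 10 test without Krt19 was chosen only after the result was seen. On array B the 4 calls became 1, Otud7b, with quantile normalisation, with a floor at the 10th percentile and with array quality weights. With a floor at the 40th percentile the 1 call was rc_AI008321_at, and with a filter at the 75th percentile it was rc_AI030650_at. Without a filter there were 3 calls, none of them among the 4. Leaving out 1 array gave 0 to 31 calls, the 31 without congenic array 5. On array C the count of 0 became 2 without a filter and 1 with an intensity trend and robust variance, and 0 to 35 with 1 array left out, the 35 again without congenic array 5. A single congenic array is then assumed to vary like the Dahl S arrays, and the same holds without congenic array 4. On array B, congenic array 5 correlated more highly with each Dahl S array (Spearman 0.948 to 0.961) than with congenic array 4 (0.940). On array C it did so with Dahl S arrays 1 and 2 (0.955 and 0.947) but not 3 (0.925), against 0.930 with congenic array 4. At an unadjusted p under 0.01 the counts were 113 on array B and 140 on array C without a filter, against 27 and 48, and 11 and 24 with the filter at the 75th percentile. More probe sets are tested without a filter and fewer with the stricter one, so these counts are not directly comparable. Without 1 Dahl S array they were 28 to 30 on array B and 25 to 47 on array C. The odds ratio for the chromosome 10 share of the changes, array B, was 4.34, and by Fisher's exact test it was 1.52 without a filter, 1.66 at an unadjusted p under 0.05 and 3.26 without Krt19, with none of these past 0.05, and 2.12 to 4.37 with 1 array left out, where the calls without Dahl S array 1 (exact p = 0.0569) and Dahl S array 2 (exact p = 0.0677) were lost. For the chromosome 10 share of the changes, array C, it was 2.68 without Krt19, and 2.43 to 5.55 with 1 array left out, the call being lost without Dahl S array 2 (Fisher's exact test p = 0.0565). On both together it kept its direction and side of the threshold with 1 array left out (2.3 to 4.32). At an adjusted p under 0.05 the odds ratio was 0 on array B and on both together, since the 1 named gene called, Otud7b, lies on another chromosome, and array C could give no value because no gene was called. The count of 1 list became 0 with an estimated correlation, 2 with both designs in one matrix, and 0 to 3 with 1 array left out. The correlation of 0.219 for the same gene on arrays B and C was 0.11 without a filter and 0.0638 to 0.319 with 1 array left out. The cause of the other changes was not tested. The single genes and probe sets reported gave 1578 values under the alternatives, of which 1539 kept their direction, none reversed a called one and 39 changed the sign of an uncalled one, while 29 called ones fell short of the threshold and 5 uncalled ones passed it. All 29 belong to the 4 probe sets called on array B, which supply only a small part of the 1578 values. Most values of these 4 under the alternatives fell short of the threshold. The filter and intensity trend settings cannot change a log2 difference, nor can the floors for values above them, so direction was fixed there. Probe sets not tested under an alternative are not counted. Signal near the floor limits what can be said of Otud7b and rc_AI008321_at in the congenic kidneys. No paired analysis was possible because the strains share no kidney numbers.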

Other observations

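The test of gene order on chromosome 10 was chosen only after the result was seen, as were the collecting duct genes named here from array A. Aqp2, the vasopressin-regulated water channel, measured 6021.7, 5434 and 6094 in the Dahl S kidneys and 8109.9 and 6484.3 on arrays 4 and 5, whose strain is not settled. Aqp3, the basolateral water channel, measured 3731.4, 4071 and 4694.6, and 6081.8 and 4787.5. The epithelial keratin Krt8 measured 1854.8, 1531.8 and 1694.6, and 1630.4 and 1811.2, and Hsd11b2 7309.3, 7365 and 8709.2, and 8039.4 and 7834.8. Avpr2 measured 2544.4, 2392.5 and 2804.5, and 3197.6 and 2960.9, with its brightest probe set. Another Avpr2 probe set was also higher on both arrays than in every Dahl S kidney, and a further one on array 5 alone. Krt18 measured 754.8, 536.7 and 725.9, and 873.4 and 765. Its other probe set gave 499.6, 544.8 and 602.1, and 633.7 and 565.1. Others were lower on array 5 than in every Dahl S kidney: Fxyd4, at 3707.7, 3648.9 and 3893, and 3669.2 and 3379.3, the sodium channel subunit Scnn1g, at 746.1, 753.8 and 803.6, and 760.7 and 684.2, and the proton pump subunit Atp6v1g3, at 1112.1, 1433 and 1343.9, and 1309.6 and 1082.

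The larger share of chromosome 10 genes among those with a small p was weighed as a pattern. Whether chance explains it cannot be settled from 5 kidneys, which make too few splits (10) for a share under 0.05: the odds ratio was 3.56 for the real split and 2.97 for the highest of the others, and of the 10 splits only 1, the real one itself, was as large. A sequence difference under single probe sets cannot be told apart from expression, because only 5 genes with a chromosome 10 probe set at an unadjusted p under 0.01 had another, Tbcd among them although its brighter probe set keeps it out of the share (median log2 difference, turned to the same direction, 0.241, 95% bootstrap interval 0.18 to 1.3). A donor segment on one part of the chromosome would bring the genes together in gene order, and the permutation p of 0.166 for 9 genes leaves that open. Regulation of these genes by the donor segment is the biological explanation of the design and may hold for some of them, but no technical one here was excluded.

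On array B the split of kidneys 2 and 4 against the rest gave 93 probe sets at an unadjusted p under 0.01, against 27 for the real split. After adjustment the real split gave 4 calls and every other 0, and what sets kidneys 2 and 4 apart there was not tested. On array C the real split gave 48 such probe sets and the highest of the others 57.

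Kidneys 4 and 5 are described as Dahl S on design A and as congenic on designs B and C, and if a number names the same kidney on all 3 designs, the deviations of a kidney from the mean of its design should correlate across designs. The mean correlation across genes of same-numbered arrays, between design A and the other two, was 0.123, and of the 120 ways to match the numbers 1 was as high, the matching by number itself (highest of the others 0.108). Of the pairs of designs, A and B had 1 of 120 ways as high, A and C 2 and B and C 3, and leaving out each kidney in turn, the matching by number had the highest mean of 24 ways. Kidneys 1 and 4 carried the mean (own mean correlations 0.208 and 0.254), while kidneys 2, 3 and 5 had 0.0476, 0.0402 and 0.0667, and kidney 2 matched another number better in every pair of designs and kidney 3 in A and C and in B and C. The same number may name the same kidney on all 3 designs, most clearly for kidneys 1 and 4, which would leave 1 of the descriptions in error, but neither which description nor the strain follows from it.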
